A study of Sedum plumbizincicola and Sedum alfredii with 13 samples.

How the data were processed

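RNA was extracted from roots and shoots of Sedum plumbizincicola and Sedum alfredii after 3 days with 0 or 10 µM CdCl2 and sequenced on an Illumina platform, per the labels. A further library, sequenced by 454 pyrosequencing from pooled roots and shoots of 6-week-old Sedum plumbizincicola, was not analysed here. The submitters' processing notes name FastQC, Bowtie and RSEM, with no versions. FastQC reports on read quality, Bowtie aligns reads, and RSEM divides reads that fit several sequences among them in proportion to estimated abundance. How the transcript set was assembled, from which reads, and how reads were trimmed is not given in the sources used here. All 12 files list the same 66584 clusters in 50837 components, 44421 of them with a single isoform.

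Per the file headers, the authors deposited an expected count, a TPM, an FPKM and an isoform-weighted length for each cluster. The deposited expected counts are RSEM estimates and were exactly whole (no tolerance) in 98.7% to 99.4% of the values above 0 per library; they were rounded to whole counts for the tests. The deposited TPM values, which the authors scaled to the same sum in each library, entered an alternative test, and the deposited FPKM values were not tested. Total rounded counts ranged from 1260160 to 4670429 per library, so 3 counts, the upper limit that 0 reads allow, correspond to between 0.642 and 2.38 CPM before normalisation. Intervals and limits cover counting error only, since reads are not independent molecules. Both species were measured against one transcript set, so a read of either species may have aligned less well to sequence taken from the other, and reads of near-identical copies can be divided between clusters; levels of members of 1 component are therefore uncertain.

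The files do not pair the cluster IDs with gene names (0 matched), so IDs are given as deposited and at most 2 higher and 2 lower IDs per comparison are named. The gene lists fixed before the data were examined (metal transport, metal chelation, iron deficiency, sulfate assimilation, cell wall, lignin, oxidative stress, heat shock, photosynthesis and root cell markers) were not used here for that reason, and neither were their tests.

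Groups came from the labels. The main tests used edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr on the design, the robust quasi-likelihood F-test, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The Cd responses in roots and shoots, their difference and the untreated root-to-shoot contrast came from 1 fit of the 8 Sedum plumbizincicola libraries by group, with 19935 clusters, 4 residual degrees of freedom and a common biological coefficient of variation of 0.178. The species contrasts came from a fit of all 12 libraries with terms for species and tissue and for Cd within each tissue, with 24074 clusters, 6 residual degrees of freedom and a coefficient of variation of 0.185. Printed adjusted p-values are from these edgeR fits unless another tool is named, and printed CPM use TMM factors over all 12 libraries. Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 2.77 to 12.1), so each counted as a separate library. No group holds more than 2 libraries and the labels do not say whether a library stands for 1 plant or several.

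For Sedum alfredii, with 1 library per group, log2 ratios of CPM used a prior count of 2, and transcripts were counted at 4-fold or more with at least 10 reads in 1 of the libraries. A fold against a group at 0 reads is a lower bound computed with 3 counts over the group, with the reads of the other group taken as exact. The named transcripts were those with the highest and lowest log2 fold change among calls with an average log2 CPM of at least 1 and groups that do not overlap; for Sedum alfredii, those with the highest and lowest ratio among transcripts with at least 100 reads in the higher library. This rule, the designs and the alternatives listed below were fixed before the data were examined. Random lists (10000 draws) were matched on expression in 10 bins.

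The tests were checked on simulated counts with known changes. These were planted only in transcripts above a minimum mean CPM, so the recovery rates do not cover the transcripts with the fewest reads. edgeR recovered 62% of 4-fold and 1% of 2-fold changes for Cd in roots, 54% and 1% for Cd in shoots, 72% and 6% for species in roots and 79% and 10% for species in shoots, with 0 or 1 unchanged transcripts called. In the same simulations limma on log2(TPM + 1) recovered 3% and 0% of the 4-fold Cd changes in roots and shoots. It called 366 and 265 unchanged transcripts in the species contrasts of roots and shoots. The simulated TPM used the effective lengths of each library. In untreated roots, isoform-weighted lengths differed by more than 1.1-fold between the species in 54.9% of 9458 clusters with several isoforms. Transcripts with equal simulated counts could thus differ in TPM, so these calls do not show that limma's species counts are false. Alternatives were DESeq2 1.42.0 size factors, DESeq2's Wald test, limma 3.58.1 on log2(TPM + 1), no filter on low counts, a minimum of 10 reads in every library, a 2-fold minimum, a replicate block, smaller or larger sets of libraries in a fit, other dose terms, and each library left out in turn.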

Results

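The data comprised 12 Illumina RNA-seq libraries from roots and shoots of a pair of related succulents. Sedum plumbizincicola accumulates cadmium (Cd) and zinc to unusually high leaf concentrations and is called a hyperaccumulator, while the Sedum alfredii plants came from a non-hyperaccumulating ecotype. Plants had received 0 or 10 µM CdCl2 for 3 days. Sedum plumbizincicola had 2 libraries, A and B, for each tissue and dose (8 libraries), which the labels call biological replicates, and Sedum alfredii had 1 library for each (4 libraries). Expression was given for 66584 assembled transcript clusters, here called transcripts, which carry only component numbers and no gene names. Each library held between 1260160 and 4670429 estimated reads, so counting error is smaller for the 4 Sedum alfredii libraries (3434922 to 4670429) than for the Sedum plumbizincicola libraries (1260160 to 2403858). Levels below are library-size normalised read counts in CPM, as mean ± SD with the number of libraries.

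The first comparison asked how the hyperaccumulator's roots responded to Cd. In Sedum plumbizincicola roots 21 transcripts rose under Cd and 394 fell, among 19935 tested. The largest rise was that of c35564_g3, from 3.68 ± 0.258 CPM (SD, n = 2) in untreated roots to 189 ± 101 CPM (SD, n = 2) with Cd, a log2 fold change of 5.65 (SE 0.48, adjusted p = 8.03e-05, higher in both treated libraries). The transcript c38292_g1 rose from 0 reads to 11 reads (3.22 ± 0.925 CPM, SD, n = 2, adjusted p = 0.0365), 4.48-fold higher with 3 counts set for the 0 reads. The 11 reads were taken as exact, so 4.48-fold is not a firm lower bound. Among the transcripts that fell, c30243_g1 went from 18.23 ± 3.92 CPM (SD, n = 2, 74 reads) to 0 reads, at least 20.2-fold lower (adjusted p = 0.00104), and c29737_g1 from 17.7 ± 2.28 CPM (SD, n = 2, 78 reads) to 0 reads, at least 21.3-fold lower (adjusted p = 0.00066).

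The transcripts that fell formed a distinct group. Of the 394, 366 had no read in any Sedum alfredii library and 383 had at most 5 reads over the 4 Sedum plumbizincicola shoot libraries. Among the 19935 tested these were 1963 and 1332. Their median length was 682 bases, against 1185 for all tested transcripts. Their median log2 fold change was -4.02 (interquartile range -4.67 to -3.40), and -3.80 with the 54 transcripts at 0 reads under Cd set to the limit of 3 counts. Together they held 2.03% of the reads of untreated root library A (95% exact binomial interval 2.01% to 2.05%) and 1.89% of those of library B (1.87% to 1.90%). With Cd the shares were 0.235% (0.227% to 0.244%) and 0.181% (0.174% to 0.187%), an order that follows from the choice of these transcripts as lower in the same 4 libraries. The transcripts that rose had a median log2 fold change of 2.098 (interquartile range 1.67 to 3.01), and 18 of these 21 had at least 10 reads in Sedum alfredii.

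**Figure D1:**
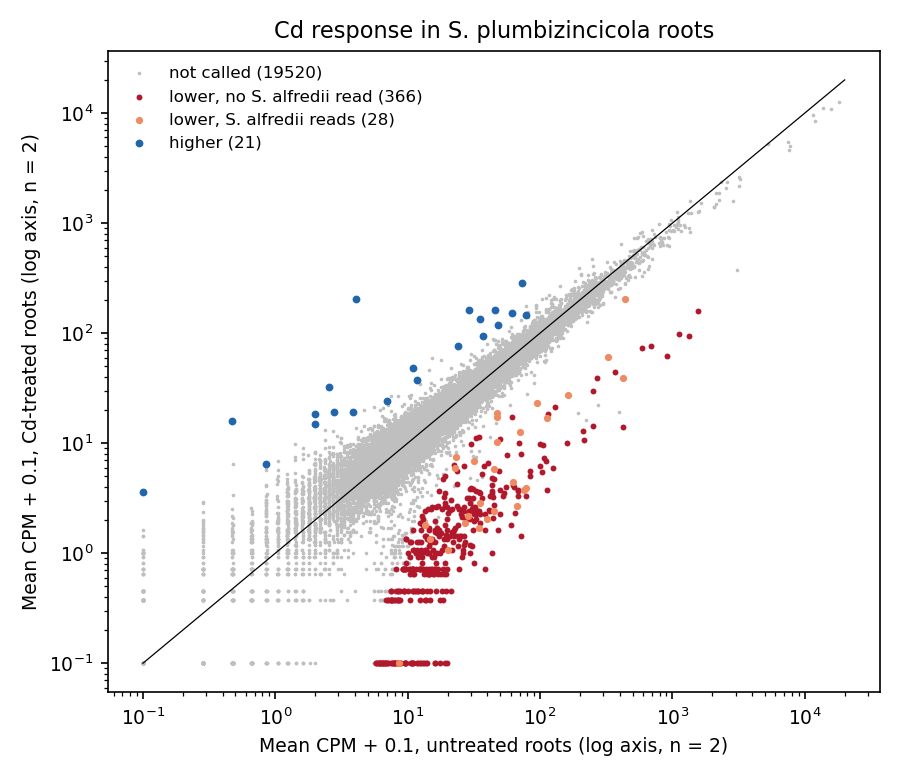
Mean CPM + 0.1 of the 19935 tested transcripts in untreated (x axis) and Cd-treated (y axis) Sedum plumbizincicola roots, both log axes, 2 libraries each; the line marks equal levels. The 366 transcripts that fell and had no Sedum alfredii read form a band below the line, while the 21 that rose lie above it.

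**Figure D2:**
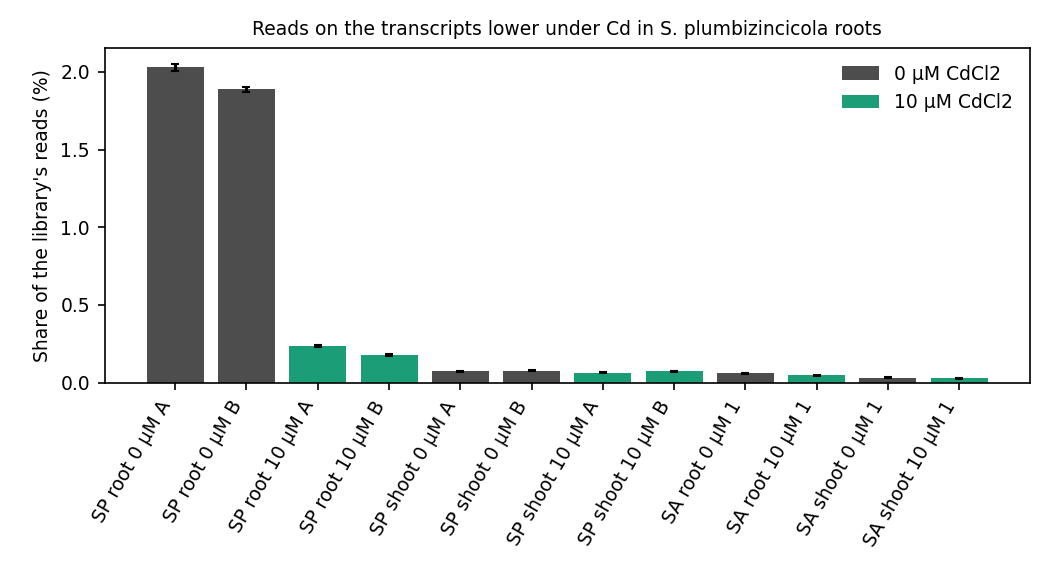
Share of each library's reads (%) on the 394 transcripts that fell under Cd in Sedum plumbizincicola (SP) roots, with 95% exact binomial intervals, for all 12 libraries; SA is Sedum alfredii and the last letter or number the replicate. The transcripts were chosen as lower with Cd in the 4 SP root libraries; the untreated ones stand at 2.03% and 1.89%, and every SP shoot and SA library is under 0.1%.

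The calls in roots came from edgeR's quasi-likelihood test over the 8 Sedum plumbizincicola libraries, and their number depended on settings: DESeq2's Wald test called 181, and the counts without Cd-treated root library A, Cd-treated root library B or untreated root library B were 252, 199 and 276. Of the calls themselves, 18 higher and 21 lower transcripts had at least 10 reads in Sedum alfredii. A separate fit to such transcripts alone called 27 (11 higher, 16 lower), and one to transcripts with at least 10 reads in every Sedum plumbizincicola library called 7 (6 higher, 1 lower). DESeq2 called neither the rise of c38292_g1 nor the fall of c30243_g1. The former was also not called in the fit to transcripts with Sedum alfredii reads (adjusted p = 0.352) or when any 1 of the 4 root libraries or either Cd-treated shoot library was left out.

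In Sedum plumbizincicola shoots no transcript passed the main test for a Cd response, which had no replicate block. With a replicate block 5 transcripts were called, though the labels do not say that the letters mark shared plants. edgeR called 0 of 19935, with 469 at an unadjusted p under 0.05 and a smallest adjusted p of 0.222, while DESeq2 called 1 and limma on log2(TPM + 1) called 0. The edgeR count was 5 without untreated shoot library B, 2 without untreated root library A and 22 without a filter on low counts. The 14 root-raised transcripts with at least 10 shoot reads had shoot log2 fold changes between -0.44 and 0.51 (median -0.04), with 6 above 0 and 8 below. Of the 9 root-lowered transcripts with such reads 8 were below 0 and 1 above (median -0.23, range -2.50 to 0.15), and no transcript of either list passed the test. In simulated shoots of this depth and spread 54% of planted 4-fold changes and 1% of planted 2-fold changes were recovered. The planted transcripts all stood above a minimum mean CPM. These rates are edgeR's, and DESeq2 recovered 6% of the 2-fold changes. Most responses of 2-fold would thus have been missed with 2 libraries per group at this depth.

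Whether the Cd response differed between roots and shoots of Sedum plumbizincicola was tested directly. The interaction test of edgeR called 0 of 19935 transcripts (528 at an unadjusted p under 0.05, smallest adjusted p 0.065), so the fall of the 394 transcripts in roots was not shown to differ from their behaviour in shoots, where 383 of them had at most 5 reads. DESeq2 called 1 transcript for this difference, and limma on log2(TPM + 1) called 306, of which 293 had the more negative change in roots. An edgeR fit with a replicate block also called a few transcripts, with the number given below. The edgeR count was 1 without untreated root library B, 1 without Cd-treated root library B and 12 without a filter on low counts. Across the 19935 transcripts the log2 fold changes in roots and shoots had a Pearson correlation of 0.0979 (Spearman 0.0596), and 0.0255 and 0.065 from the A and B pairs of libraries alone. This is a correlation across genes, which are not independent replicates. With 0 calls in shoots, the observed and the chance overlap of calls were both 0.

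The roots and shoots of untreated Sedum plumbizincicola differed in the majority of tested transcripts. Of 19935, 5423 were higher in roots and 5065 higher in shoots. The highest root-to-shoot difference was that of c32971_g3, at 1269 ± 62.5 CPM (SD, n = 2) in roots and 0 reads in shoots, at least 1668-fold higher (adjusted p = 2.04e-10), followed by c30786_g1 at 431 ± 51.9 CPM (SD, n = 2) in roots and 0 reads in shoots, at least 557-fold higher (adjusted p = 1.25e-09). In the other direction c45296_g4 stood at 1543 ± 130 CPM (SD, n = 2) in shoots and 0 reads in roots, at least 2194-fold (adjusted p = 1.29e-10), and c37610_g1 at 507 ± 85.2 CPM (SD, n = 2) in shoots and 0 reads in roots, at least 725-fold (adjusted p = 5.40e-10). The median log2 fold change was 1.75 among root-higher and -1.99 among shoot-higher transcripts, or 1.80 and -1.97 with groups at 0 reads set to 3 counts. These calls came from the same edgeR fit, and 5363 were called with a minimum of 10 reads in every library, a filter that removes transcripts silent in a tissue.

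The next comparisons set the hyperaccumulator against the non-hyperaccumulator. In roots 8099 transcripts were higher in Sedum plumbizincicola and 8214 higher in Sedum alfredii, of 24074 tested. The transcripts c35671_g2 and c23181_g1 led the first group, at 1600 ± 1490 CPM (SD, n = 4) and 795 ± 753 CPM (SD, n = 4) in Sedum plumbizincicola roots and 0 reads in both Sedum alfredii root libraries, at least 4753-fold and 2423-fold higher (adjusted p = 4.55e-05 and 1.74e-08). Their wide spread follows the Cd dose: c23181_g1, one of the 394 transcripts above, stood at 1441 ± 164 CPM (SD, n = 2) without Cd and 148 ± 49.0 CPM (SD, n = 2) with it, and c35671_g2 at 2850 ± 627 CPM and 349 ± 88.1 CPM (SD, n = 2 each), with an adjusted p of 0.0611 for its Cd response. In Sedum alfredii roots c2654_g1 and c14216_g1 reached 2179 ± 753 CPM (SD, n = 2) and 1571 ± 680 CPM (SD, n = 2) with 0 reads in the 4 Sedum plumbizincicola root libraries, at least 5758-fold and 4169-fold higher (adjusted p = 6.85e-11 and 6.87e-11). Each of these SDs spans an untreated and a Cd-treated library, not replicates: 1647 and 2712 CPM for c2654_g1, and 1090 and 2052 CPM for c14216_g1.

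In shoots 7677 transcripts were higher in Sedum plumbizincicola and 8170 higher in Sedum alfredii, of 24074 tested. The leading Sedum plumbizincicola transcripts were c40179_g4 at 361 ± 84.8 CPM (SD, n = 4) and c59214_g1 at 357 ± 58.5 CPM (SD, n = 4), both with 0 reads in Sedum alfredii shoots and at least 640-fold and 628-fold higher (adjusted p = 7.64e-11 and 2.07e-11). The leading Sedum alfredii transcripts had 0 reads in Sedum plumbizincicola shoots and were carried by the Cd-treated library. c30066_g1 stood at 108 CPM in the untreated and 21280 CPM in the Cd-treated Sedum alfredii shoot, at least 26560-fold higher than in Sedum plumbizincicola (adjusted p = 1.16e-10), and c28859_g1 at 147 and 1405 CPM, at least 1944-fold higher (adjusted p = 6.51e-11). Both bounds pool the reads of both doses, so they do not hold for the untreated shoot alone. The Cd-treated library held 53852 of the 54152 Sedum alfredii shoot reads of c30066_g1. The fit took the Cd effect as equal in both species, and edgeR without the dose term did not call c30066_g1 (adjusted p = 0.0833).

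Over all 12 libraries 6394 transcripts had at least 10 reads in Sedum plumbizincicola and none in Sedum alfredii, 6043 the reverse, and 20488 at least 10 in both species. Of the 8099 transcripts higher in Sedum plumbizincicola roots, 5167 were also higher in its shoots (2583 for independent lists), and of the 8214 lower in roots 5683 were also lower in shoots (2788 for independent lists). In the opposite direction in shoots were 349 of the 8099 and 358 of the 8214. Both contrasts came from 1 fit on 1 transcript set, so poorer alignment of 1 species' reads could also raise this overlap. The species tests used edgeR over all 12 libraries with the Cd effect within a tissue taken as equal in both species, because Sedum alfredii had 1 library per tissue and dose. Among the 10146 transcripts with at least 10 reads in every library 5938 differed in roots and 6830 in shoots, and limma on log2(TPM + 1), where the median of all transcripts shifted by 0.55 toward Sedum plumbizincicola, split the shoot calls into 9559 higher and 4819 lower.

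The species difference depended on the tissue for 5143 of 24074 transcripts. The ratio of Sedum plumbizincicola to Sedum alfredii was higher in roots for 2579 of them and higher in shoots for 2564. This sign does not say which species was higher in either tissue. The transcript c42683_g1 was at 320 ± 126 CPM (SD, n = 2) in untreated Sedum plumbizincicola roots and 0 reads in its shoots, against 7.73 and 3.97 CPM in untreated Sedum alfredii roots and shoots (log2 difference 12.08, SE 1.06, adjusted p = 1.16e-05). In contrast c35284_g2 had 0 reads in Sedum plumbizincicola roots and 22.7 ± 4.13 CPM (SD, n = 2) in its untreated shoots, against 8.23 and 0.722 CPM in Sedum alfredii (log2 difference -13.38, SE 1.18, adjusted p = 4.76e-06). The number of such transcripts was 2896 without the untreated and 3053 without the Cd-treated Sedum alfredii root library, and 1909 from untreated libraries alone. On the TPM scale 8641 were called, with 1900 of them positive and 6741 negative, where the median of all transcripts shifted by -0.68.

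In Sedum alfredii the Cd response rests on 1 library per dose, so it has no replicate check and no test. In roots 93 transcripts were at least 4-fold higher and 166 at least 4-fold lower with Cd, of 23652 with at least 10 reads in 1 of the libraries. The largest ratios in roots were those of c37195_g2, with 12 reads untreated and 581 with Cd (41.4-fold, exact counting interval 23.5 to 80.6), and c26845_g1, with 2 and 162 reads (69.3-fold, 18.9 to 577). In the other direction c59866_g1 had 133 and 0 reads, at least 51.8-fold lower, and c19922_g1 had 112 and 2 reads (65.5-fold lower, 17.7 to 547).

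In the Sedum alfredii shoot 252 transcripts were at least 4-fold higher and 122 at least 4-fold lower with Cd, of 18679. The 252 higher transcripts took 0.808% of the reads of the untreated shoot library (95% exact binomial interval 0.799% to 0.816%) and 9.38% of those of the Cd-treated library (9.35% to 9.41%). That order follows from the choice of these transcripts in the same libraries, and the intervals cover counting error only. The transcript c31686_g1 had 0 reads without Cd and 2674 with it, at least 976-fold higher, and c27749_g1 had 1 and 3238 reads (3545-fold, counting interval 636 to 140000). The lowest ratios were those of c37058_g1, with 128 and 2 reads (58.5-fold lower, 15.9 to 488), and c45248_g1, with 3717 and 245 reads (13.9-fold lower, 12.2 to 15.8).

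Set beside these 259 and 374 transcripts, the same count between doses in Sedum plumbizincicola was 539 and 806 for the A and B root pairs and 57 and 30 for the A and B shoot pairs. Between replicate libraries of Sedum plumbizincicola it was 277 and 162 in roots without and with Cd, and 113 and 49 in shoots. The 374 of Sedum alfredii shoots exceed both replicate shoot pairs, and the 259 of its roots lie between the replicate root pairs at full depth. The species difference in the Cd response was not tested, and the Sedum alfredii libraries are deeper. Thinned to the 1260160 reads of the smallest library, the counts were 169 and 355 in Sedum alfredii roots and shoots and 454, 470, 45 and 27 in the Sedum plumbizincicola dose pairs, against 130 and 61 between replicate root libraries and 100 and 34 between replicate shoot libraries. The place of the Sedum alfredii root count thus depended on the setting: it was above both replicate root pairs after thinning and with a minimum of 50 reads (72 against 52 and 13), and between them with TPM ratios (429 against 460 and 197) and with a 2-fold threshold (1857 against 1896 and 1584).

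**Figure D3:**
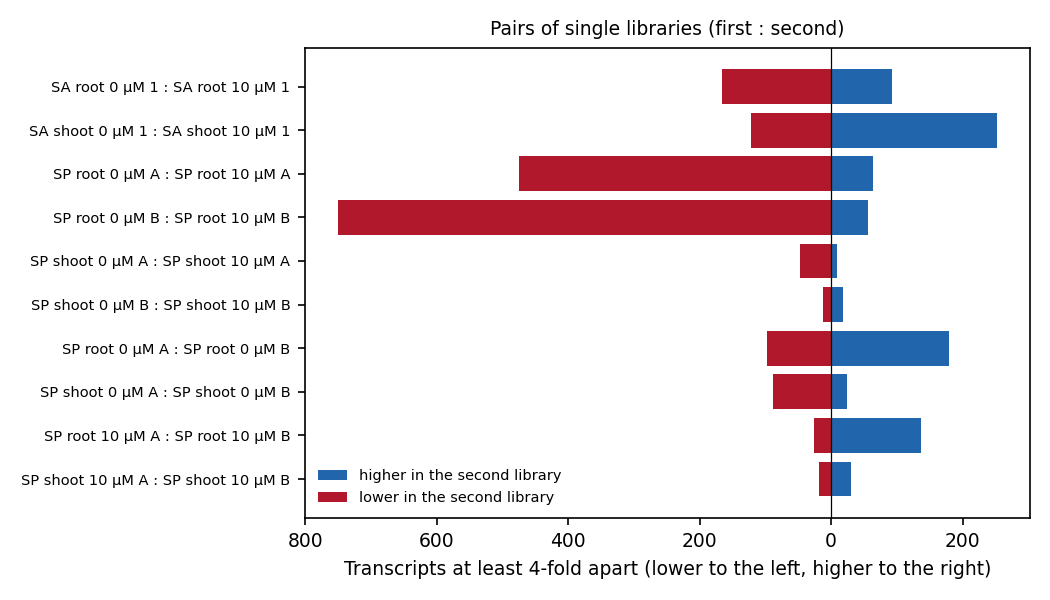
Number of transcripts at least 4-fold higher (right) or lower (left) in the second library of each pair, among those with at least 10 reads in 1 of the libraries; SA is Sedum alfredii, SP Sedum plumbizincicola, and the last letter or number the replicate. Root pairs of SP between doses show 475 and 750 lower transcripts, and the SA shoot pair shows 252 higher ones.

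The Cd responses of the species were then compared in each tissue. The transcripts that rose under Cd in Sedum plumbizincicola roots were also higher with Cd in Sedum alfredii roots: of the 17 measured there, 16 were higher, 6 of them at least 2-fold, with a median log2 ratio of 0.80. This median lay above all 10000 random lists of the same size matched on expression (95% of lists between -0.17 and 0.18). The lists drew transcripts singly, while c35564_g1, c35564_g2 and c35564_g3 among the 17 belong to 1 component and are not independent. The leading transcript c35564_g3 stood at 212 CPM in the untreated and 1049 CPM in the Cd-treated Sedum alfredii root. Of the 394 transcripts that fell, 19 were measured in Sedum alfredii roots, where 13 were lower and 6 higher (median log2 ratio -1.08, below all 10000 random lists, 95% between -0.17 and 0.26). Of these 19, 10 were at least 2-fold lower and 1 at least 2-fold higher. All 9 transcripts with 13 to 58 Sedum alfredii reads were lower (median log2 ratio -1.21). Of the 10 with at least 100 reads 6 were higher and 4 lower (median log2 ratio 0.21). These 4 had log2 ratios from -1.31 to -1.17, and the 6 higher ones from 0.042 to 1.03.

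Across all measured transcripts the relation was weak. The Pearson correlation across genes between the Sedum alfredii log2 ratio and the Sedum plumbizincicola log2 fold change was 0.137 over 16052 transcripts in roots and -0.0186 over 14791 in shoots. The shoot value changed sign between the replicate pairs of Sedum plumbizincicola, at -0.0649 with pair A and 0.0498 with pair B, so no agreement in shoots was detectable. Genes are not independent replicates, and these values describe the libraries at hand.

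Root-only transcripts were also picked without regard to the Cd dose, as those with at least 100 reads over the 4 Sedum plumbizincicola root libraries and at most 5 over its 4 shoot libraries. Of the 159 that had no read in Sedum alfredii, 114 had a log2 ratio under -2 between Cd-treated and untreated roots and 27 stayed between -1 and 1. Of the 281 that had at least 10 reads in Sedum alfredii, 16 were under -2 and 248 stayed between -1 and 1. Among the 159, 113 were also among the transcripts called lower above, and among the 281, 15 were. The ratios came from the same root libraries as those calls, so they are not a separate check of the fall.

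**Figure D4:**
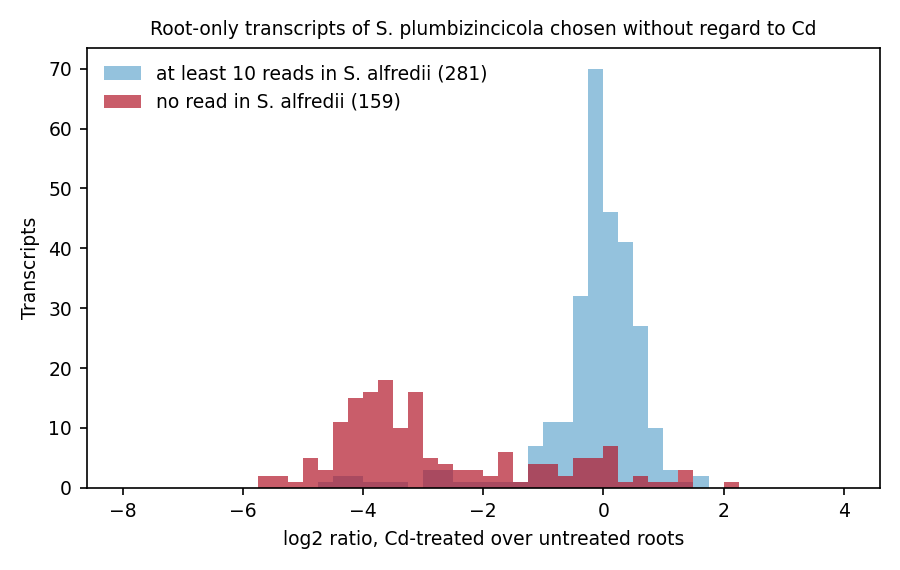
Histogram of the log2 ratio of Cd-treated to untreated Sedum plumbizincicola roots (pooled reads of 2 libraries each, x axis) for root-only transcripts, with the number of transcripts on the y axis. The 281 transcripts with Sedum alfredii reads centre near 0 (median -0.03), and the 159 without such reads have a median of -3.31.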

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

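The tests of this part were chosen before their results were seen, except that the root-to-shoot contrast was set beside the component pairs afterwards. A difference between the tissues flagged 5143 transcripts, called by the interaction test of edgeR for the species contrast in roots against shoots. The named transcripts among them had log2 differences of 12.08 (c42683_g1), 11.20 (c34286_g2), -13.38 (c35284_g2) and -12.17 (c27180_g2). Each had 0 reads in the roots or in the shoots of Sedum plumbizincicola, so these sizes are values of the fit and not measured folds. The last of these, c27180_g2, had 1 read in the 4 Sedum alfredii libraries against 253 reads in untreated Sedum plumbizincicola shoots and 0 in its roots, so its value rests on that 1 read (adjusted p = 0.0312), and over the alternatives the adjusted p ranged from 1.63e-05 to 1, the latter without the library that holds it. For c34286_g2 the contrast rests on Sedum alfredii, at 604 CPM in the untreated shoot and 1 read in the untreated root, against 1 read over all 8 Sedum plumbizincicola libraries; its adjusted p of 0.00635 ranged from 8.13e-09 to 1 over the alternatives and was 1 without the Cd-treated Sedum alfredii root library or without Cd-treated Sedum plumbizincicola root library A. No group held 4 or more libraries, so no library was tested as standing apart.

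Most transcripts differed between the species in both tissues. If the calls came from transcripts with few or no reads in 1 species, few would remain among well-measured ones, but 58.5% of the 10146 transcripts with at least 10 reads in every library were called in roots. If copies of 1 gene from each species had been kept as separate members of a component, called members of a component would go in opposite directions more often than permuted directions do, and 38.8% of 4015 such pairs did in roots, under the permuted range of 48.5% to 51.5% but above the 19.4% of 1594 pairs in the root-to-shoot contrast. That last value shows that members of a component tend to move together, so the permuted range was a wrong bound, and separate copies cannot be told apart from a true difference by this test. A poorer alignment of 1 species' reads to sequence assembled from the other was not tested and also stays open, as do differences in how the plants were grown.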

How the results depend on the processing

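2 settings were chosen after seeing the data: keeping only transcripts with at least 10 reads in Sedum alfredii, and thinning to the smallest library. With 2 libraries per group, leaving 1 out leaves a lone library that is assumed to vary like the others. Over the alternatives, 109 counts or correlations of the comparisons stayed within 1.5 times the main count or within the replicate spread, 37 moved further and 2 changed sign, and for the named transcripts 348 values kept their side of the threshold, 17 missed it and none changed sign. The 17 concern c38292_g1, c30243_g1 (DESeq2 alone), c30066_g1 (no dose term, adjusted p = 0.0833, over its alternatives 3.71e-132 to 0.0833), c34286_g2 and c27180_g2. The gene list alternatives were not run, since no names were matched. The cause was not tested except where a filter's construction gives it.

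DESeq2's Wald test called 181 transcripts for Cd in roots against 415, 1 for Cd in shoots and 1 for their difference, against 0 in both. Without a filter the counts were 716, 22 and 12, and 27073 for species in roots against 16313. With at least 10 reads in every library, which by construction removes transcripts silent in a group, they were 7 for Cd in roots, 1 for the difference between tissues, 5363 for root against shoot against 10488, 5938 for species in roots and 6830 in shoots against 15847. A separate fit to transcripts with reads in Sedum alfredii called 27 for Cd in roots. limma on log2(TPM + 1) called 306 for the difference of the Cd response and 8641 for the species difference between tissues, against 5143, which was 1909 from untreated libraries alone. On that scale the median of all transcripts shifted by 0.17 for Cd in roots, 0.12 for its difference between tissues, 0.12 for root against shoot, -0.11 and 0.55 for species in roots and shoots, and -0.68 for their difference.

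With each library left out, counts ranged from 199 to 406 for Cd in roots, 0 to 5 for Cd in shoots, 0 to 1 for their difference, and 2896 to 5071 for the species difference between tissues. The labels do not say that a replicate letter marks shared plants, and deviations of same-letter libraries correlated at 0.0942 to 0.326 between groups. With a replicate block 5 transcripts were called for Cd in shoots and 6 for the difference between tissues, and the other counts of that fit stayed within 1.5 times.

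For Sedum alfredii, a 2-fold threshold gave 1857 transcripts in roots and 2251 in shoots, a minimum of 50 reads 72 and 238, TPM ratios 429 in roots, and thinning 169 in roots. For the agreement of Cd responses between species, Spearman's rho was 0.0993 in roots and 0.00900 in shoots, where it reversed the sign; pair A gave 0.0890 in roots and pair B 0.0498 in shoots, again reversed. Between roots and shoots of Sedum plumbizincicola the correlation was 0.154 at an average log2 CPM of at least 3, and rho was 0.0596. With 2 libraries per group at these depths, simulations recovered 62% and 54% of 4-fold and 1% of 2-fold Cd responses in roots and shoots; depth and replication were not varied separately.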

Other observations

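The description of the Sedum alfredii shoot and the tissue contrast below was chosen after the data were seen, as were the tests on untreated root library A, on an even draw of plant genes and on expression in shoots. The 252 transcripts at least 4-fold higher in the Cd-treated Sedum alfredii shoot were followed in the other libraries. Of the 198 measured in Sedum alfredii roots, 49 were at least 2-fold higher and 3 at least 2-fold lower with Cd (median log2 ratio 0.44). Of the 118 measured in Sedum plumbizincicola shoots, 2 were at least 2-fold higher and 14 at least 2-fold lower (median log2 fold change -0.17). In Sedum alfredii roots, 107 of the 166 transcripts at least 4-fold lower with Cd and 51 of the 93 higher ones had no read in Sedum plumbizincicola, against 3388 of all 23652. In its shoots these were 19 of the 122 lower and 45 of the 252 higher ones, against 1499 of all 18679.

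The root-to-shoot contrast of untreated Sedum plumbizincicola was largely shared by Sedum alfredii. Of 4239 transcripts higher in Sedum plumbizincicola roots and measured in Sedum alfredii, 3531 (83.3%) were higher in the Sedum alfredii root, and of 4197 higher in shoots 3544 (84.4%) were higher in its shoot. The Pearson correlation across 16288 transcripts was 0.782. The isoform-weighted length of clusters with several isoforms differed by more than 1.1-fold between the species in 54.9% of 9458 clusters in untreated roots, against 17.8% between replicate root libraries of Sedum plumbizincicola.

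The 394 transcripts that fell under Cd in Sedum plumbizincicola roots allow several explanations. An unusual untreated root library A does not account for most of them, since a fit without that library still called 288 lower and 52 higher transcripts, and 286 of its calls were among the 415 in the same direction. An even draw from root-specific plant genes does not either, since 94.3% of the 383 with at most 5 shoot reads had no Sedum alfredii read, against 47.5% to 55.6% in random lists matched on expression from a pool of 1332 that includes the 383, and 31.9% among the 949 of the pool that were not called. Hypothesis: part of this RNA may come from another organism on untreated roots. The test took all transcripts of such an organism to shrink by 1 factor with Cd, an assumption that was not itself tested. Among the 114 root-only transcripts with a log2 ratio under -2 the spread was 1.56 times that of counting noise around 1 factor. This lies between the bounds of 1.5 and 2 set beforehand. The value was 2.38 among the 16 with Sedum alfredii reads and 2.41 among 31 other tested transcripts with a log2 ratio under -2. The observed SDs of these 3 sets were close (0.717, 0.791 and 0.7495), while their counting SDs were 0.46, 0.333 and 0.311. The values thus differ mainly through counting noise and do not show a tighter scatter among the 114. Counting noise leaves out the spread between replicate root libraries (chi-square per degree of freedom 12.1 without and 3.18 with Cd). Transcripts that shrink by 1 factor could therefore also exceed it, and the set was cut at -2 on the ratio itself. Such RNA cannot be told apart from a joint fall of the plant's own species-specific root transcripts. The spread lies between bounds that cover counting noise alone, and no sequence or name was used.

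Cd calls appeared in Sedum plumbizincicola roots and not in its shoots. Of the 415 root calls 5.54% had at least 10 reads over the 4 shoot libraries, namely 9 of the 394 lowered and 14 of the 21 raised transcripts. This goes with the hypothesis that most of the lowered transcripts are too little expressed in shoots to be called there. It does not hold for most of the raised ones. Lower power in shoots stays open: simulated 4-fold changes were recovered less often in shoots by a difference of -8 percentage points (SE 6.96), which cannot be told apart from the bound of -10. The 14 root-raised transcripts with shoot reads had a median shoot log2 fold change of -0.04, while of the 9 root-lowered ones 8 were below 0 in shoots as in roots (median -0.23), and the interaction test called none of either list.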
